A study of Arabidopsis thaliana with 12 samples.

How the data were processed

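The data are 12 Agilent dual-colour arrays of RNA from 10-day-old Arabidopsis thaliana seedlings. Per the labels, seeds were kept 3 days at 4 °C, grown at 22 °C under 16 h of light and 8 h of dark, and both genotypes of an array shared a plate; 0.5 µg of total RNA was amplified and labelled. The pHS::SACL3 seedlings and their acl5-1 controls had, per the labels, 30 min of heat shock at 37 °C and were collected 30 or 210 min later. The design text states 3 biological replicates; the labels give Col-0 as the background of acl5-1 and Ler as that of acl5-4. Arrays were grouped by their labels into 4 comparisons of 3 arrays: Col-0 against acl5-1, acl5-1 pHS::SACL3 against acl5-1 at 30 min and at 210 min, and acl5-4 ajax2-31 against acl5-4. The test genotype was in Cy5 on 7 arrays and in Cy3 on 5. No control RNA was shared between comparisons as far as the labels state.

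Per the file headers, spots were read with Feature Extraction 9.5.1.1 (protocol GE2-v5_95_Feb07), and the headers name the build ath1:Jan2004. The deposited scanner files hold spot and background signals in intensity units, as mean brightness per spot with no background subtracted, and also processed signals that the program had background-subtracted and dye-normalised. Their ratio column is, per the file headers, a log10 ratio of Cy5 over Cy3 processed signal. The deposited series value table holds log2 ratios of the test genotype over its control for up to 33338 probes per array. Unit and sign were checked against the scanner ratios, where the size of the correlation was 0.988 to 0.999 per array and its sign negative on the 5 arrays with the test genotype in Cy3. How the authors made the series table is not given in the sources used here.

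Analysis started from the scanner mean signals and local background medians. Background was corrected by normexp with an offset of 50, each array was normalised by loess with a span of 0.3 in which control spots and spots marked as outliers had no weight, and outlier spots (6 to 160 per array) were then set to missing. Up to 19 spots per channel were saturated. Repeated spots of a probe were averaged. There were 43803 spots that were not controls, 1417 control spots and 43603 probes. Probes were paired with genes through their accession (34285), another accession (325), the gene name (1685) or the description (22) and the RefSeq table of loci and symbols; 7 matched several genes and 7279 none, and these were left out. Each gene was represented by its brightest probe (7155 tested genes had more than 1). Genes well above background in at least 1 channel on at least 3 of the 12 arrays were tested: 21425 of 26400, leaving out 4975; 152 array values among them were missing. Where a genotype was below background on all 3 arrays, the fold is given as a bound.

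Ratios of all 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with a signed column for each comparison and a dye term (residual degrees of freedom 7, prior 6.03). The dye effect itself passed in 2380 genes. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and the 210 min minus 30 min difference was tested as a contrast. The fit ties the estimates of different comparisons only weakly, with error correlations of 0.0303 in size. Median SDs between the 3 arrays of a comparison, with the dye effect left in, were 0.171, 0.144, 0.174 and 0.145 log2 for Col-0, 30 min, 210 min and ajax2-31. No pair of arrays held identical values (0 pairs). The arrays came from 3 slides: slide 1 held Col-0 replicates 1 and 3, 30 min replicate 2 and 210 min replicate 1; slide 2 held Col-0 replicate 2, 30 min replicate 3 and 210 min replicates 2 and 3; slide 3 held 30 min replicate 1 and ajax2-31. The number of arrays limits the precision.

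The 19 gene lists were SACL family, polyamine metabolism, LHW-TMO5 module and its targets, procambium and cambium, xylem transcription factors, xylem secondary wall, xylem cell death, lignin monomer synthesis, phloem, cytokinin, auxin response, cell cycle, gibberellin metabolism, heat shock, stress and defence, anthocyanin and flavonoid, photosynthetic tissue, root endodermis and root hair, and shoot meristem. Below, the LHW-TMO5 module or list, where counted or tested, means the list of the module and its targets. The lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. Camera compares a list with all other genes, and a list's direction is camera's. Over the 4 comparisons camera made 34 calls, 7 up and 27 down, of which 13 held with an estimated correlation, and fry, which does not compare a list with other genes, made 26. For cytokinin genes the estimated correlation was −0.0129, below the preset, yet the camera adjusted p in Col-0 rose from 0.0239 to 0.0894. A call lost with an estimated correlation therefore does not by itself show correlated genes. Sign agreement is the percent of genes changed in Col-0 with the same sign elsewhere. Crowding of changed genes within 5 Mb of ACL5, and of SACL3 for ajax2-31 (odds ratio 1.05), was tested with Fisher's exact test.

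Named genes followed a rule: SACL3 and ACL5 first, then the other SACL genes; the 10 highest and 10 lowest log2 ratios among changed genes with the same sign on 3 arrays, leaving out loci with no symbol unless among the top 3 (5 and 5 for the difference between times, where 1 gene passed); and from each list up to 2 rising and 2 falling genes with the smallest adjusted p, or the leading gene where none passed. Exceptions are said to be named after their values were seen; AHP6, TMO5 and PXY at 210 min and VSP1 in Col-0 are also of this kind. The lists, thresholds, comparisons, this rule and all alternatives but one were fixed before the data were examined; the exception, added after seeing the data, leaves out genes within 5 Mb of ACL5. Counts of shared genes without 1 array were also added then. Alternatives were no background correction, the processed signals, median centring, quantile scaling of mean brightness, other filters, no dye term, single-comparison fits, the mean of probes, array weights, slide or replicate number as a block, the series values, leaving out each array, a 2-fold threshold and treat at 1.5-fold. Slide as a fitted term or fixed block was a separate dye effect for each slide in place of the shared one. The random block also acted on Cy5 over Cy3 ratios, and a shift of test over control by slide was not fitted.

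The fit was tested on simulated data, with changes planted in 67, 67 and 66 of 21425 genes at log2 sizes of 0.5, 1 and 2. At 0.5 it recovered 71.6% for Col-0, 85.1% at 30 min, 83.6% at 210 min, 74.6% for ajax2-31 and 16.4% for the difference between times, and at 1 between 95.5% and 100%. False calls were 4.71% to 6.9% of calls. The simulated noise was normal and independent for each gene and array, and each gene's dye effect was the same on all arrays. Slide effects and correlation between genes were not simulated, so the rates on the real arrays may differ.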

Results

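Transcript levels were measured in 10-day-old Arabidopsis seedlings on 12 dual-colour arrays, each of which set a test genotype directly against an acl5 mutant grown on the same plate. There were 4 comparisons with 3 arrays each: wild type Col-0 against acl5-1; acl5-1 carrying pHS::SACL3, a heat-inducible copy of the bHLH gene SACL3, against acl5-1 at 30 min and at 210 min after a heat shock; and the double mutant acl5-4 ajax2-31 against acl5-4. ACL5 encodes thermospermine synthase, and the design text describes Col-0, pHS::SACL3 and ajax2-31 as genotypes that suppress the acl5 mutant, so each comparison asks which transcripts differ when the mutant state is relieved. Positive log2 ratios are higher in the test genotype. Of 26400 genes with a probe, 21425 were bright enough to test, and between 66.4% and 73.6% of probes stood well above background in each channel of each array. Median spot signal ran from 361 to 828 in Cy3 and from 116 to 348 in Cy5, over median local backgrounds of 58 to 79.5 and 35 to 43. Log2 ratios of all genes correlated across replicate arrays, after removal of the dye effect, with r from 0.572 to 0.732 for Col-0 and from 0.516 to 0.691 for ajax2-31. The range was −0.0448 to 0.379 at 30 min and −0.121 to 0.346 at 210 min of pHS::SACL3; genes are not independent replicates. The number of arrays limits the precision of every estimate. Every gene named as changed had the same sign on all 3 of its arrays unless stated.

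Col-0 against acl5-1 asks how the loss of thermospermine synthase changes the seedling transcriptome, read here from the side of the wild type. Genes of xylem formation were lower in Col-0, from members of the LHW-TMO5 transcription factor module and auxin response through the VND and MYB regulators to cellulose synthases of the secondary wall and proteases of vessel cell death. As lists, with an estimated correlation, only the LHW-TMO5 module and the xylem transcription factors were still called. Anthocyanin genes, and a smaller number of stress genes, were higher. Of these stress genes KIN1 and VSP1 lie near ACL5, and COR15A lost its call without any 1 of the arrays. Of 21425 genes, 2401 changed (limma, Benjamini-Hochberg), 1105 higher and 1296 lower, and 64 and 243 of them changed by at least 2-fold. The same sign was seen on all 3 arrays for 2332 of the 2401. Without replicate 2 the count was 1411 and without replicate 3 it was 1547; of 52 named genes that passed, between 7 and 11 lost their call without 1 array, among them DFR, UF3GT, COR15A, CA1 and PAO5.

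ACL5 itself (AT5G19530) was 7.81-fold lower in Col-0, at a log2 ratio of −2.96 (SE 0.11, n = 3; limma adjusted p = 2.47e-09), and lower on each array (−3, −2.78 and −3.09). The labels do not give the lesion of acl5-1, so this level does not check the genotype. The ACL5 probe lies on chromosome 5 from 6589193 to 6589252 and the SACL3 probe on chromosome 1 from 10494143 to 10494202, in the coordinates of the array files. BUD2, whose S-adenosylmethionine decarboxylase supplies the aminopropyl donor for thermospermine, fell with it at −3.31 (SE 0.13; limma adjusted p = 2.47e-09). PAO5, a polyamine oxidase, was slightly higher at 0.27, and 14 of the 17 polyamine genes did not pass. SACL3 (AT1G29950) was lower at −0.41 (SE 0.093; limma adjusted p = 0.0112; arrays −0.61, −0.35 and −0.25), a call lost without replicate 1 (−0.30) or replicate 2 (−0.43). Its relatives SACL1, SACL2 and SAC51 stood at −0.13, 0.073 and −0.034 and did not pass.

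**Figure D1:**
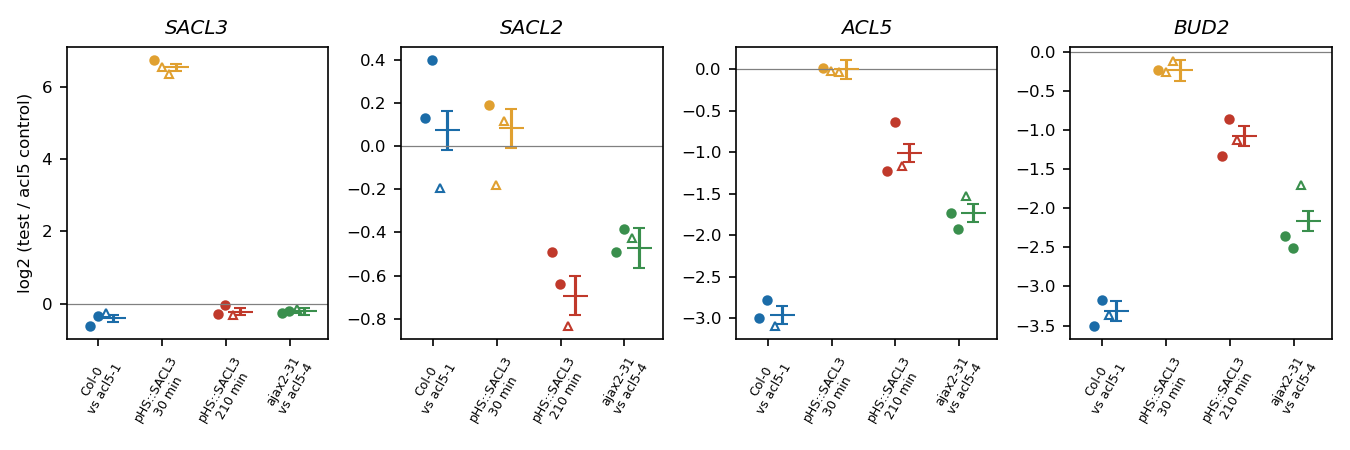
Log2 ratio (test genotype over its acl5 control, vertical axis) of SACL3, SACL2, ACL5 and BUD2 on each of the 12 arrays (horizontal axis, by comparison); filled circles mark arrays with the test genotype in Cy5, open triangles those with it in Cy3, and bars give the fitted estimate with its standard error. SACL3 stands at 6.54 at 30 min after heat shock and at −0.22 at 210 min, while ACL5 is at −2.96 for Col-0, −1.01 at 210 min and −1.73 for ajax2-31.

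Early vascular regulators were lower in Col-0. T5L1 and LHL3, partners in the bHLH dimer that drives vascular cell division, fell by 1.86 and 1.28 on the log2 scale. LOG4, their cytokinin-activating target, was at −1.73, the moving root transcription factor SHR at −1.05 and the bHLH gene TMO5 at −1.13. Of 15 measured genes of the LHW-TMO5 module, 9 were lower, 0 higher and 6 did not pass (mean −0.649, median −0.502; camera adjusted p = 4.06e-09, and 0.0373 with an estimated correlation). The auxin response factor MP (−1.40), the class III HD-ZIP genes ATHB8 (−1.88) and PHB (−1.11), and the receptor kinase PXY (−1.45) were lower too. In procambium and cambium 8 of 20 genes were lower and 1 higher, the peptide gene CLE41 at 0.39; the camera adjusted p was 0.000456, but 0.16 with an estimated correlation. Auxin response was lower in 13 of 25 genes, among them IAA1 (−1.17) and IAA19 (−1.15), and none was higher. The camera adjusted p of auxin response was 1.55e-10, and 0.0894 with an estimated correlation. Cytokinin genes were lower in 6 of 29, with CRF5 at −0.63 and the oxidase CKX6 at −0.36 (camera adjusted p = 0.0239, and 0.0894 with an estimated correlation).

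Xylem differentiation genes showed the deepest drop among the lists. The vessel NAC regulators VND1 (−2.78), VND2 (−2.17) and VND3 (−2.25) were all lower, as were the master switches VND6 (−1.77) and VND7 (−1.40) and their target MYB46 (−1.49). Altogether 18 of 21 xylem transcription factors were lower and none was higher (mean −1.1; camera adjusted p = 2.02e-26, and 0.047 with an estimated correlation). Secondary wall genes were lower in 19 of 21, including the cellulose synthases CESA4 (−1.47), CESA7 (−1.47) and CESA8 (−1.59). For the wall list the camera adjusted p was 7.57e-25 and the mean −1.02; with an estimated correlation the adjusted p was 0.0591. All 5 genes of xylem cell death fell, with the cysteine proteases XCP1 at −1.49 and XCP2 at −1.36 (camera adjusted p = 3.52e-07, and 0.0911 with an estimated correlation). Lignin monomer synthesis was lower in 6 of 15 genes, such as CAD5 (−0.69) and 4CL1 (−0.44), and higher in F5H1 (0.30). F5H1 was higher on 2 of 3 arrays and lost its call without any 1 of them. The list's camera adjusted p was 0.000404, and 0.07 with an estimated correlation. LOG4, SHR, TMO5, PHB, PXY, VND6, VND7, MYB46 and CESA7 are named here after their values were seen. Adjusted over the list alone, 20 xylem transcription factors, 21 wall genes and 15 auxin genes were lower. By slide, the median of the xylem transcription factors was −1.01 on slide 1 (2 arrays) and −0.972 on slide 2 (1 array), and that of the LHW-TMO5 module −0.506 and −0.438. With slide fitted as a term, that is a separate dye effect for each slide, their means were −1.13 and −0.673.

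Anthocyanin and flavonoid genes were higher in 6 of 10 genes and lower in none, with DFR at 1.05 and the glucosyltransferase UF3GT at 0.91 (mean 0.522; camera adjusted p = 5.33e-05, and 0.111 with an estimated correlation). Stress and defence genes were higher in 3 of 10, namely the cold-regulated COR15A (1.09) and KIN1 (0.78) and the storage protein gene VSP1 (1.26); the camera adjusted p was 0.0279, and 0.459 with an estimated correlation, and the call was lost without replicate 2 (mean 0.337). COR15A itself was not called without any 1 of the arrays. Phloem genes split, 1 higher and 1 lower of 18, the lower being the receptor kinase BAM3 (−0.36, lower on 2 of 3 arrays). Among root genes the nitrate transporter NRT2.1 (1.2) and the phosphate transporter PHT1;1 (0.35, higher on 2 of 3 arrays) rose and 10 of 12 did not pass. The call of PHT1;1 was lost without any 1 of the arrays. The cell cycle list had 1 changed gene of 29, CYCD1;1 (0.48, higher on 2 of 3 arrays), and the gibberellin list 1 of 6, GA3OX1 (0.47). Photosynthetic genes gave CA1 at 0.52 and LHCB1.1 at −0.73. LHCB1.1 was positive on both arrays with Col-0 in Cy5 (0.84 and 0.99) and −2.73 on the other, replicate 3. Without replicate 3 LHCB1.1 was at −0.21 and not called. None of 27 heat shock genes and none of the 3 measured shoot meristem genes changed, GOLS1 standing at 0.35 and STM at −0.11. Camera called none of these last 7 lists nor the SACL family and polyamine lists (camera adjusted p from 0.256 to 0.834). Mean and median differed in sign for gibberellin (0.0208 and −0.0852), photosynthetic (−0.0431 and 0.0895) and root genes (0.0682 and −0.0306), and camera's direction was up for each.

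**Figure D2:**
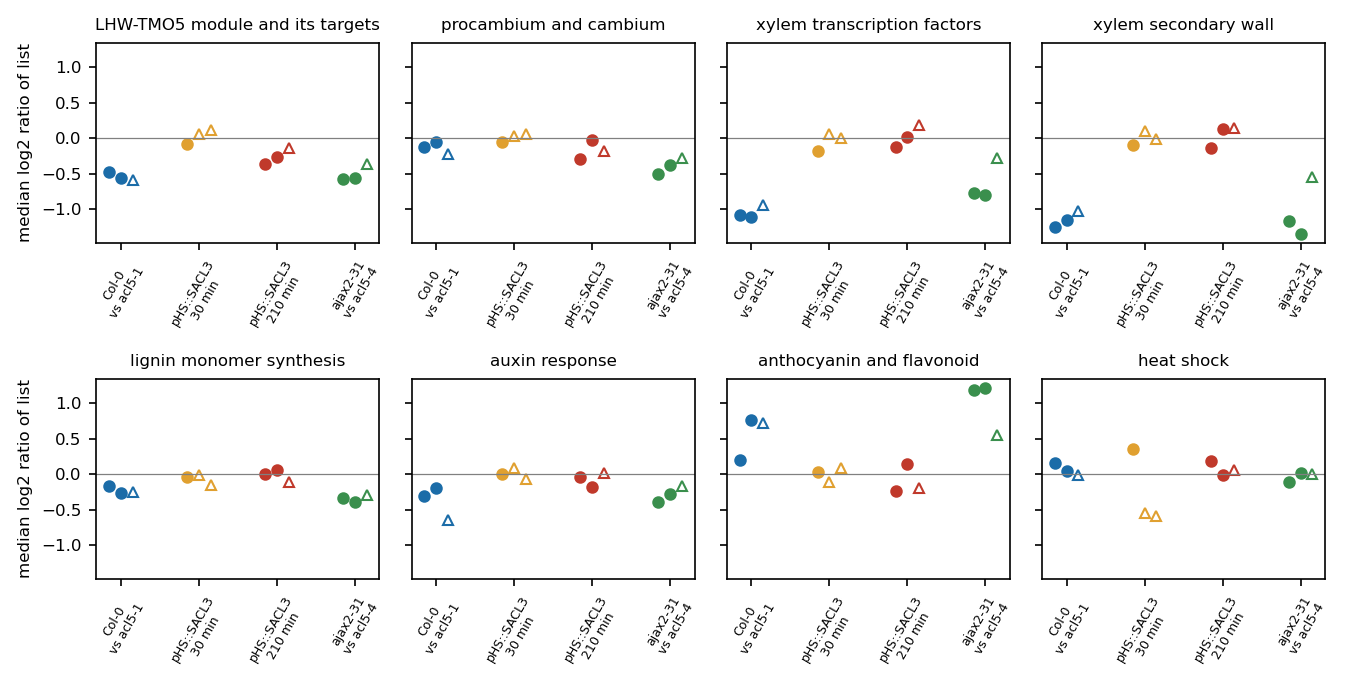
Median log2 ratio (test genotype over its acl5 control, vertical axis) of 8 gene lists on each of the 12 arrays (horizontal axis, by comparison); filled circles mark arrays with the test genotype in Cy5 and open triangles those with it in Cy3. Xylem secondary wall genes lie between −1.26 and −1.03 on the Col-0 arrays and between −1.35 and −0.555 on the ajax2-31 arrays, while the heat shock list at 30 min is at 0.353 on the array with the test genotype in Cy5, its only one on slide 3, and at −0.545 and −0.595 on the others.

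Beyond these lists, higher genes in Col-0 were TGG2, a myrosinase that hydrolyses glucosinolates, at 4.53 (SE 0.11; limma adjusted p = 3.54e-11), AT5G26270 at 4.45 and AT5G23830 at 3.94. The flowering repressor FLC was at least 8.97-fold higher, being below background on all acl5-1 arrays. The sulphur-starvation gene LSU2 followed at 2.41, the pathogen- and clock-controlled PCC1 at 2.08, the subtilase SBT3.12 at 1.87, the cryptochrome CRY3 at 1.84, the nicotinamidase NIC3 at 1.58 and the glucosidase BGLU47 at 1.51. Lower were the xyloglucan enzyme XTH3, by at least 27.6-fold and below background on all Col-0 arrays, AT5G24240 at −4.77 (SE 0.096; limma adjusted p = 6.46e-12) and AT4G36230 at −3.41. GASA2, of a gibberellin-regulated peptide family, was at least 9.43-fold lower. The cysteine desulfhydrase DES1 was at −3.29 and the subtilases SBTI1.1 and ATSBT5.2 at −2.96 and −2.77. MRD1, named after its values were seen, was at −2.22 (SE 0.241; limma adjusted p = 3.44e-05).

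Many of these genes sit near ACL5 on chromosome 5. Within 5 Mb either side of ACL5 383 of 1872 tested genes changed (20.5%), against 2018 of 19553 elsewhere (10.3%), an odds ratio of 2.23 (95% interval 1.97 to 2.53; two-sided Fisher's exact test, p = 2.41e-34). The odds ratio was 2.99 within 2 Mb and 1.92 within 8 Mb. Taken by side, a division made after the values were seen, the excess lay above ACL5: in the 5 Mb above ACL5 (higher coordinates) 243 of 669 genes changed (36.3%; odds ratio 4.96, 4.19 to 5.86), and in the 5 Mb below it 139 of 1202 (11.6%; odds ratio 1.14, 0.94 to 1.37). FLC, NIC3, AT5G23830, LSU2, CRY3, TGG2 and AT5G26270, 7 of the 10 most raised genes, lie inside the 5 Mb window, as do ACL5, AT5G24240, DES1 and BUD2 among the 10 most lowered. In ajax2-31 the same window had an odds ratio of 0.876 (0.73 to 1.04). Among changed genes with several probes, 49 of 685 had probes of both signs.

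**Figure D3:**
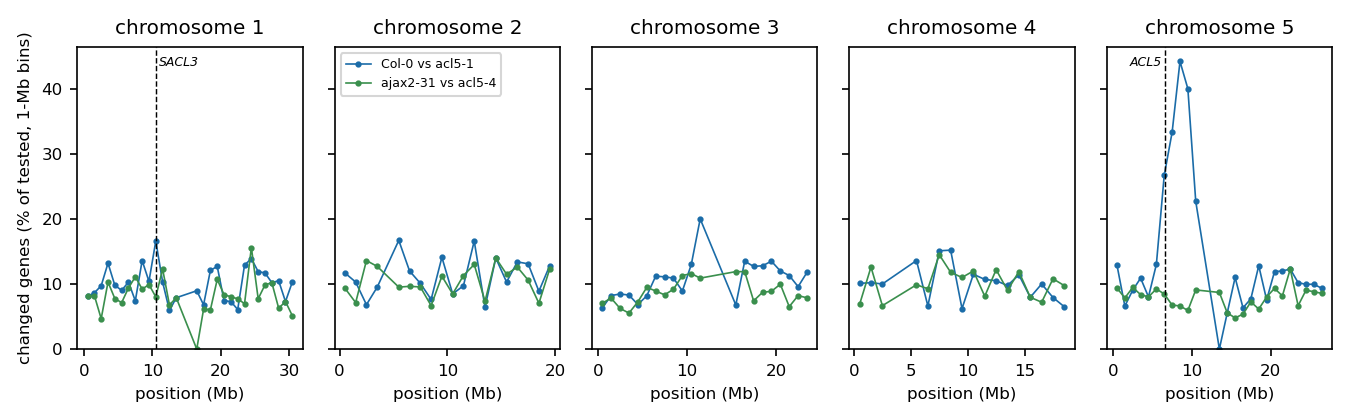
Percent of tested genes that changed (vertical axis) in each bin of 1 Mb with enough tested genes along the 5 chromosomes (horizontal axis, position in Mb), for Col-0 against acl5-1 in blue and acl5-4 ajax2-31 against acl5-4 in green, with dashed lines at ACL5 and SACL3. Col-0 peaks at 44.2% of 181 genes on chromosome 5, about 2 Mb above ACL5, while ajax2-31 has no such peak there.

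pHS::SACL3 at 30 min after heat shock asks which genes differ first when SACL3 is switched on in acl5-1. No unheated pHS::SACL3 seedlings were measured. At either time a standing difference between the lines therefore cannot be told apart from a response to SACL3. SACL3 rose strongly and few other genes were called: 13 genes changed, 7 higher and 6 lower (limma, Benjamini-Hochberg), while 525 had an unadjusted p under 0.05. Replicate arrays correlated only from −0.0448 to 0.379 here, so few calls do not show that few genes responded. The few others included plant defensin genes, which were higher, and MRD1, RDUF2 and MAF5, which were lower. No gene of the LHW-TMO5, procambium, xylem, auxin or cytokinin lists passed. Without replicate 2 there were 6 changed genes, and without replicate 3 there were 2, SACL3 and MRD1, while the defensins kept their sign and lost their call (PDF1.2 at 1.55).

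SACL3 was 93.1-fold higher at a log2 ratio of 6.54 (SE 0.093, n = 3; limma adjusted p = 7.61e-14; arrays 6.73, 6.53 and 6.35), which fits the pHS::SACL3 label at this time. ACL5 stood at 0.00036 (SE 0.11), SACL1 at 0.095, SAC51 at −0.048 and SACL2 at 0.083, above background on 1 of 3 arrays in either genotype. BUD2 was at −0.24 and did not pass. The defensin genes PDF1.2 (1.94; limma adjusted p = 0.00835), PDF1.2c (1.68), PDF1.3 (1.56) and PDF1.2b (1.44), which respond to jasmonate and ethylene, were all higher; their sequences are closely similar, and how far the probes tell them apart was not tested. CYP94C1, an enzyme that oxidises the jasmonate hormone, was at 0.76 (limma adjusted p = 0.0309). MRD1 (AT1G53480), whose function is little known, was lower at −2.99 (SE 0.24; limma adjusted p = 0.000143). AT2G13547 was at −1.06 and above background on 1 of 3 pHS::SACL3 arrays, the ubiquitin ligase gene RDUF2 at −0.68 and the FLC relative MAF5 at −0.54.

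Gene by gene no change was called in the vascular lists at 30 min, with values such as −0.17 for LOG3, −0.18 for HCA2, −0.21 for SND2, −0.21 for CESA7, −0.15 for the nuclease gene RNS3, 0.21 for GH3.3, −0.22 for LOG5, −0.13 for PAL1 and −0.10 for the phloem gene FTIP1. The camera test called 6 lists, all but the SACL family on small mean shifts. Of these the SACL family (mean 1.67, adjusted p = 4.16e-08) was carried by SACL3 and was also called with an estimated correlation (adjusted p = 0.00957). Xylem transcription factors had a mean of −0.0917 (camera adjusted p = 0.000829, and 0.658 with an estimated correlation), and with slide fitted as a term it was 0.0101 (camera adjusted p = 0.969). Lignin genes (mean −0.0703) had a camera adjusted p of 0.00993 and cytokinin genes (mean 0.0345) of 0.0342, each 0.181 with an estimated correlation. With slide as a term these means were −0.0485 and 0.0484, and neither was called. Heat shock genes had a mean of −0.17 (camera adjusted p = 0.000177, and 0.658 with an estimated correlation), yet their median was 0.353 on replicate 1 and −0.545 and −0.595 on the others, with HSP15.7 at 0.35, −0.67 and −0.78. After removal of the fitted dye effect the medians were 0.211, −0.352 and −0.471. Replicate 1 was the only array of this comparison with the test genotype in Cy5 and the only one on slide 3, so dye, slide and replicate are confounded there. Photosynthetic genes had a mean of −0.199 (camera adjusted p = 0.000829, and 0.181 with an estimated correlation), with RCA at −0.35; their array medians were 0.146, −0.597 and −0.859, and −0.334, −0.00268 and −0.282 after removal of the dye effect. Several calls were lost without 1 array: heat shock without replicate 3 (mean −0.0187, with camera's direction turned to up), xylem transcription factors without replicate 3 (mean −0.0806), lignin without replicate 1 (−0.0684) or 3 (−0.0483), photosynthetic genes without replicate 1 (−0.125) or 3 (−0.143), and cytokinin without any 1 of them (0.0182 to 0.0492).

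The other 13 lists were not called at 30 min (camera adjusted p from 0.0661, for xylem secondary wall, to 0.92, for xylem cell death). Xylem cell death, at a mean of −0.0411, was 0.218 and called with slide fitted as a term (camera adjusted p = 0.000888), and 0.0997 and not called with slide as a random block (camera adjusted p = 0.164). In stress and defence PDF1.2 alone of 10 genes passed, with a list mean of −0.0105. Uncalled leaders of the remaining lists were the anthocyanin regulator PAP1 at −0.41, CYCD1;1 at −0.16, the root gene CASP5 at 0.32 and the meristem gene CUC2 at −0.090; GA20OX2 was below background in both genotypes. Camera's direction was up while the mean was negative for auxin (−0.00434), cell cycle (−0.00536, median 0.00354), gibberellin (−0.0085), root (−0.00539) and anthocyanin genes (−0.00684, median 0.0187).

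At 210 min after heat shock the same line asks what differs from acl5-1 after the pulse of SACL3, again without unheated seedlings as a reference. SACL3 was no longer higher than in acl5-1, and 114 genes changed, 97 of them lower and 17 higher (limma, Benjamini-Hochberg; 741 with an unadjusted p under 0.05). The lower genes included ACL5, BUD2 and MP, while no xylem transcription factor changed. Of the 15 measured genes in the list of the LHW-TMO5 module and its targets, 3 were lower (LOG4, SHR and AHP6). Of the 114, 1 was at least 2-fold higher and 18 at least 2-fold lower. Without replicate 1 the count was 25 and without replicate 3 it was 9; ACL5 (−0.92), BUD2 (−0.97), SACL2 (−0.68), MP (−0.62), LOG4 (−0.61) and SHR (−0.43) kept their sign without replicate 3 but lost their call.

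SACL3 stood at −0.22 (SE 0.093, n = 3) and did not pass, so at this time it does not check the label. ACL5 was lower at −1.01 (SE 0.11; limma adjusted p = 0.00126; arrays −1.22, −0.64 and −1.16) and BUD2 at −1.08 (limma adjusted p = 0.00144), the changed genes among 17 of polyamine metabolism. SACL2 fell by 0.69 (limma adjusted p = 0.00332), while SACL1 (−0.17) and SAC51 (−0.24) did not pass. The SACL list was lower in camera (mean −0.333, adjusted p = 1.24e-07, and 0.00697 with an estimated correlation).

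In the list of the LHW-TMO5 module and its targets, LOG4 was lower at −0.80 (limma adjusted p = 0.013) and SHR at −0.51 (limma adjusted p = 0.0117). AHP6, an inhibitor of cytokinin signalling, was at −0.50 (limma adjusted p = 0.0293). None of the module's own bHLH genes passed. The list had 3 lower genes of 15, or 9 lower and 1 higher when adjusted over the list alone. Its mean was −0.24 (camera adjusted p = 4.93e-12, and 0.00697 with an estimated correlation). Its median was −0.319 on slide 1 (1 array) and −0.241 on slide 2 (2 arrays), and its mean −0.249 with slide fitted as a term. TMO5 (−0.60) did not pass, with a limma adjusted p of 0.0885. In procambium and cambium MP alone passed, at −0.70 (SE 0.081; limma adjusted p = 0.00144), and PXY at −0.45 did not. The procambium mean was −0.17 (camera adjusted p = 1.06e-10, and 0.0427 with an estimated correlation), with medians of −0.221 and −0.0685 on slides 1 and 2. Auxin response had no changed gene of 25, its leader PIN6 being at −0.77 (limma adjusted p = 0.0895), and a mean of −0.11 (camera adjusted p = 5.42e-06, and 0.402 with an estimated correlation).

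No gene of the xylem lists was called higher, though adjusted over the list alone 2 xylem transcription factors were. Xylem transcription factors led with MYB46 at 0.32, below 0 on 1 of 3 arrays, and their list mean was 0.0728 (camera adjusted p = 0.0108, and 0.754 with an estimated correlation). With slide fitted as a term the mean was 0.0473 and the list was not called (camera adjusted p = 0.115), nor was it without replicate 2 (mean 0.0364) or replicate 3 (mean 0.0769). Secondary wall genes had a mean of 0.0783 (camera adjusted p = 0.036, and 0.789 with an estimated correlation), which was −0.00722 without replicate 2, although WAT1, a vacuolar auxin transporter needed for fibre walls, was lower at −0.77. XCP1 was at 0.21 and xylem cell death was not called (mean 0.162, camera adjusted p = 0.109). Root genes were lower as a list (mean −0.0787; camera adjusted p = 0.00694, and 0.754 with an estimated correlation), with no gene passing and NRT2.1 at −0.28; without replicate 1 their mean was −0.00367 and the call was lost.

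The remaining 11 lists were not called at 210 min (camera adjusted p from 0.177 to 0.869), and no gene of them passed other than ACL5 and BUD2. Their leading members were COMT1 at 0.17, SMXL3 at 0.14, CRF5 at −0.42, CYCD3;3 at −0.11, GA2OX2 at −0.24, HSP22 at 0.20, PDF1.2 at 0.60, LHCB2.1 at −0.24 and STM at 0.079. PAP2, which led the anthocyanin list, was below background on all acl5-1 arrays and above it on 1 of 3 pHS::SACL3 arrays. Median and mean differed in sign for polyamine (0.0278 and −0.0936), lignin (−0.00475 and 0.00391, camera down) and cytokinin genes (0.00366 and −0.00459).

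Outside the lists MRD1 was again the most lowered gene at −3.70 (SE 0.24; limma adjusted p = 2.11e-05). The iron-deficiency bHLH genes BHLH100 (−1.96) and bHLH38 (−1.45), XTH3 (−1.83), GASA2 (−1.59), the jasmonate methyltransferase JMT (−1.16), ATSBT5.2 (−1.07), the myrosinase-binding protein MBP1 (−1.07) and the sulphate transporter SULTR3;2 (−1.06) followed. Higher were AT3G08490 at 1.1 (limma adjusted p = 0.000749), AT2G47670 at 0.93, the amine oxidase AO1 at 0.67, CAD6 at 0.62, the formin Fh5 at 0.56, the ROP effector RIC2 at 0.51 and TBL38, of a family that acetylates wall polymers, at 0.50. Of 23 named genes that passed at 210 min, 13 lost their call without replicate 1 and 19 without replicate 3, which left MRD1, GASA2, JMT and AT3G08490.

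Between the times SACL3 alone of 21425 genes differed by the limma test of the difference, although with slide as a fixed or a random block the count was 36 or 35 genes and with array weights 42. SACL3 fell by 6.77 on the log2 scale from 30 to 210 min (SE 0.13; adjusted p = 5.36e-12); 561 genes had an unadjusted p under 0.05. Within slide the difference was −6.84 on slide 1 and −6.56 on slide 2. The LHW-TMO5 list was lower at 210 min than at 30 min (mean difference −0.221; camera adjusted p = 5.65e-08, and 0.0249 with an estimated correlation), as was the SACL list, through SACL3 (mean −2; adjusted p = 0.00089 with an estimated correlation). Fry did not call the difference of the LHW-TMO5 list (fry adjusted p = 0.0821). Without replicate 1 of 30 min the count of genes was 6, and without replicate 2 of 210 min it was 8.

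acl5-4 ajax2-31 against acl5-4 asks which transcripts a second-site suppressor shifts in a mutant of another background, labelled Ler. Many vascular genes that were lower in Col-0 were lower here too: 8 of 9 in the LHW-TMO5 module, 8 of 8 in procambium and cambium, 16 of 18 xylem transcription factors, 15 of 19 wall genes, 3 of 5 cell death genes and 4 of 6 lignin genes. Anthocyanin genes were higher, as in Col-0. Changed genes numbered 1894, 674 higher and 1220 lower (limma, Benjamini-Hochberg), with 46 and 153 changed by at least 2-fold and 1820 of one sign on all 3 arrays. Without replicate 1 the count was 891 and without replicate 2 it was 1047; SACL2, CLE41, COR15A, BAM3 and CVP2 were among 12 of 54 named genes that lost their call without replicate 1. All 3 arrays lay on slide 3, so no second slide gives a value.

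ACL5 was lower at −1.73 (SE 0.11, n = 3; limma adjusted p = 1.54e-06; arrays −1.73, −1.92 and −1.53) and BUD2 at −2.16 (SE 0.13), the changed members of the polyamine list. SACL3 stood at −0.21 (SE 0.093; limma adjusted p = 0.203) and did not pass. SACL2 (−0.47; limma adjusted p = 0.00523) and SAC51 (−0.49; limma adjusted p = 0.038) were lower, SAC51 losing its call without any 1 of the arrays, and SACL1 (−0.12) did not pass. The SACL list had a mean of −0.325 (camera adjusted p = 0.0136, and 0.0731 with an estimated correlation).

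T5L1 fell by 1.93 (SE 0.086; limma adjusted p = 9.32e-08), and SHR was at −1.06. In the LHW-TMO5 module 10 of 15 genes were lower and none higher (mean −0.65; camera adjusted p = 4.86e-13, and 0.0119 with an estimated correlation). ATHB8 and PXY stood at −1.42 each, and procambium and cambium had 10 of 20 genes lower against 2 higher, CLE41 (0.37) and the LOB-domain gene LBD3 (0.66). The procambium mean was −0.451 (camera adjusted p = 8.96e-08, and 0.0489 with an estimated correlation). VND2 (−1.71) and MYB46 (−1.23) led the xylem transcription factors, 16 of 21 lower (mean −0.776; camera adjusted p = 1.13e-19, and 0.0489 with an estimated correlation). CESA4 and CESA8, each at −1.31, led the wall genes, 15 of 21 lower (mean −0.845; camera adjusted p = 5.86e-21, and 0.0489 with an estimated correlation). With slide fitted as a term the means were −0.623 for the LHW-TMO5 module, −0.73 for the xylem transcription factors and −0.781 for the wall genes. XCP1 (−1.19) and XCP2 (−1.01) were lower among 3 of 5 cell death genes; the camera adjusted p was 0.000189, and 0.176 with an estimated correlation. The cell death medians were −1.15 and −1.14 on replicates 1 and 2 but 0.0572 on replicate 3, the reverse-labelled array, and −0.881, −0.861 and −0.0749 after removal of the dye effect. Medians of the xylem transcription factors were −0.776, −0.802 and −0.287.

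Lignin monomer genes were lower in 8 of 15, with the entry enzyme PAL1 at −0.70 and 4CL1 at −0.68, against F5H1 at 0.59 (mean −0.322; camera adjusted p = 6.58e-08, and 0.0197 with an estimated correlation). Adjusted over the list alone, 13 lignin genes were lower. Auxin response was lower in 12 of 25, with GH3.3 at −1.18 and IAA19 at −0.84 (camera adjusted p = 2.43e-08, and 0.101 with an estimated correlation), and cytokinin response in 10 of 29, with CRF5 at −0.64 and ARR9 at −0.41, not called without replicate 3 (camera adjusted p = 0.0126, and 0.0489 with an estimated correlation), a call lost without replicate 3 (mean −0.185). Root genes were lower in 4 of 12, with the endodermal genes CASP5 at −0.80 and ESB1 at −0.45 (camera adjusted p = 0.00195, and 0.303 with an estimated correlation), and array medians of −0.365, −0.403 and 0.0084. Anthocyanin genes were higher in 7 of 10 and lower in none, DFR at 2.06 (limma adjusted p = 1.82e-05) and UF3GT at 1.59 (mean 0.973; camera adjusted p = 8.86e-12, and 0.035 with an estimated correlation).

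Lists not called in ajax2-31 had camera adjusted p from 0.0651 to 0.966. Phloem genes CVP2 (−0.45) and BAM3 (−0.43) were lower and the sulphate transporter SULTR2;1 (0.81) higher, as SULTR2;1 was in Col-0 (0.70). In stress and defence COR15A was at 1.28 and RAB18 at −0.73, among heat shock genes GOLS1 at 0.89 and HSP23.6 at −0.70, and among gibberellin genes GA3OX1 at 0.35 and GA2OX2 at −0.42. Photosynthetic LHCB1.1 (−0.72, lower on 1 of 3 arrays) and RCA (−0.48, lower on 2 of 3) passed with the dye effect fitted. Without replicate 1 the calls of RCA (−0.28), LHCB1.1 (−0.63), CVP2 (−0.35), BAM3 (−0.35), COR15A (1.07), RAB18 (−0.74), HSP23.6 (−0.51), GA3OX1 (0.39) and GA2OX2 (−0.34) were lost. Without replicate 2 all of these but BAM3 and GA2OX2 were not called either, and without replicate 3 GA3OX1 and RAB18 were not. No cell cycle gene of 29 and no shoot meristem gene of 3 passed, CYCB1;4 at −0.30 and KNAT1 at −0.21; 4575 genes in all had an unadjusted p under 0.05. Polyamine genes had a median of 0.00772 and a mean of −0.219, and the meristem list's mean of −0.0257 stood against camera's direction, up.

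The most lowered genes in ajax2-31 were AT4G36230 at −2.92, XTH3 at −2.39 (above background on 1 of 3 double-mutant arrays) and AT3G10080 at −2.29. The thioredoxin TRX1 (−2.23), the galactosidase AGAL2 (−2.16), the subtilase SBTI1.1 (−2.07), the laccase LAC6 (−1.96) and the auxin influx carrier LAX2 (−1.92; limma adjusted p = 8.07e-07) came next. Most raised beside DFR were AT4G22870 (2.04), the thioredoxin TH8 (1.87), the anthocyanin transport protein TT19 (1.80), the glucosidase BGLU18 (1.76), bHLH38 (1.47), the defensin PDF2.1 (1.46), BHLH100 (1.44; 0.95 and not called without replicate 3) and the glutathione transferase GSTF14 (1.42). MRD1, named after its values were seen, was at −0.14. Centring each array on its median in place of loess moved the median of all genes to −0.244 in this comparison, and 12347 genes then passed, 2739 higher and 9608 lower; 1362 of the 1894 were among them.

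**Figure D4:**
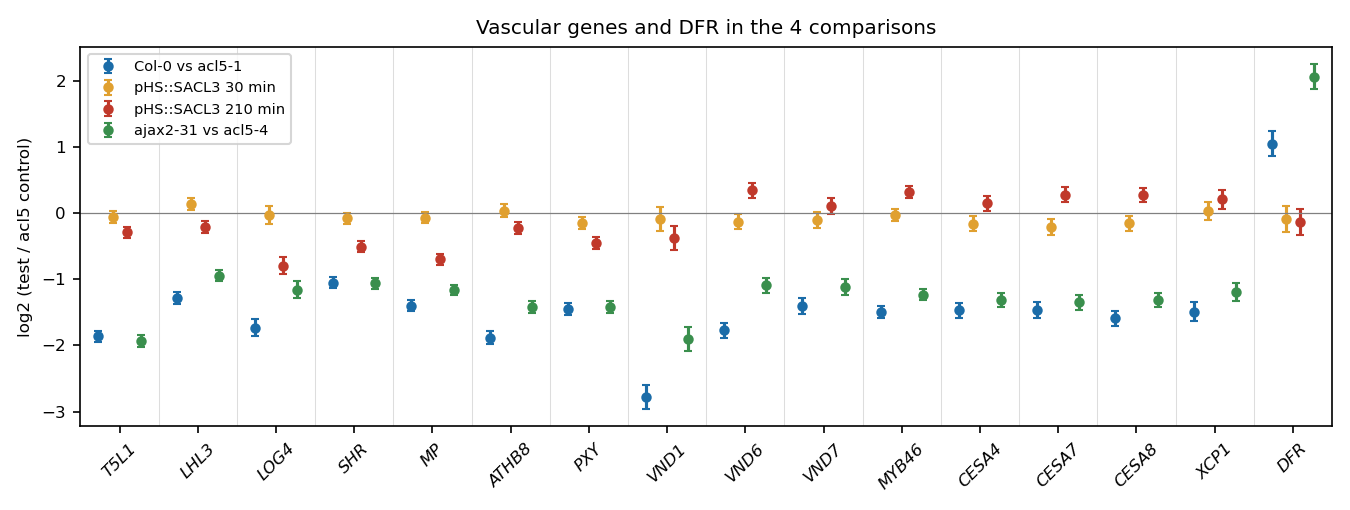
Fitted log2 ratio (test genotype over its acl5 control, vertical axis) with its standard error (bars) for 16 genes picked after their values were seen, 15 vascular genes and DFR (horizontal axis), in the 4 comparisons (colours), from 3 arrays each. T5L1 is at −1.86 in Col-0 and −1.93 in ajax2-31, whereas MYB46 is at −1.49 and −1.23 there but 0.32, not passing, at 210 min of pHS::SACL3.

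Set side by side, the Col-0 response was shared most with ajax2-31. Of 2401 genes changed in Col-0, 74.3% had the same sign in ajax2-31 (1082 of the 1296 lower and 703 of the 1105 higher). The share was 56% at 210 min of pHS::SACL3 (697 lower and 648 higher) and 52.4% at 30 min (848 lower but only 409 higher). At 30 min the genes lower and the genes higher in Col-0 were thus both mostly below 0, so the 848 do not show a shared response. Single arrays, with the dye effect left in, gave 69.6%, 77.5% and 69.2% in ajax2-31, 57.8%, 60.2% and 48.6% at 210 min, and 50.7%, 43.1% and 52.2% at 30 min, each of the last below the fitted share. Both comparisons called 794 genes, 599 lower in both, 144 higher in both and 51 opposite, where chance would give 73.8, 34.8 and 104. Col-0 and 210 min shared 93 called genes, 77 of them lower in both against 5.87 by chance, 2 higher in both against 0.877 and 14 opposite against 6.03; without 210 min replicate 1 the genes lower in both numbered 20, and without replicate 3 they numbered 7. Across all genes r with Col-0 was 0.471 for ajax2-31 (Spearman's rho 0.257), 0.14 for 210 min (−0.0234) and 0.00561 for 30 min (−0.0418); genes are not independent replicates. The 210 min and 30 min comparisons shared 4 called genes, all lower in both.

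A set of 65 genes was lower in Col-0, at 210 min of pHS::SACL3 and in ajax2-31, and 0 were higher in all of these. Its size rested on 2 of the 210 min arrays: without replicate 1 it was 16 genes and without replicate 3 it was 4. ACL5 and BUD2 belonged to it, with log2 ratios given above. From the lists it held LOG4 (−1.73, −0.80 and −1.16), SHR (−1.05, −0.51 and −1.06), MP (−1.40, −0.70 and −1.16) and WAT1 (−1.16, −0.77 and −0.98). Chosen after their values were seen, other members were the auxin influx carrier LAX2 (−2.20, −0.69 and −1.92), the auxin synthesis gene YUC2 (−1.81, −0.81 and −1.09), the brassinosteroid receptor relative BRL2 (−1.03, −0.52 and −1.24), the strigolactone synthesis gene CYP711A1 (−0.65, −0.62 and −1.15), the laccase LAC6 (−2.52, −1.03 and −1.96) and the xylogen protein gene XYP2 (−1.15, −0.51 and −1.34). In contrast bHLH38 and BHLH100 were lower at 210 min and higher in ajax2-31, 2 of the 14 genes with opposite signs among 84 called in both; no test compared the responses of these genes between the comparisons. Neither was called at 210 min without replicate 1 or without replicate 3 of that time, nor BHLH100 in ajax2-31 without its replicate 3.

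**Figure D5:**
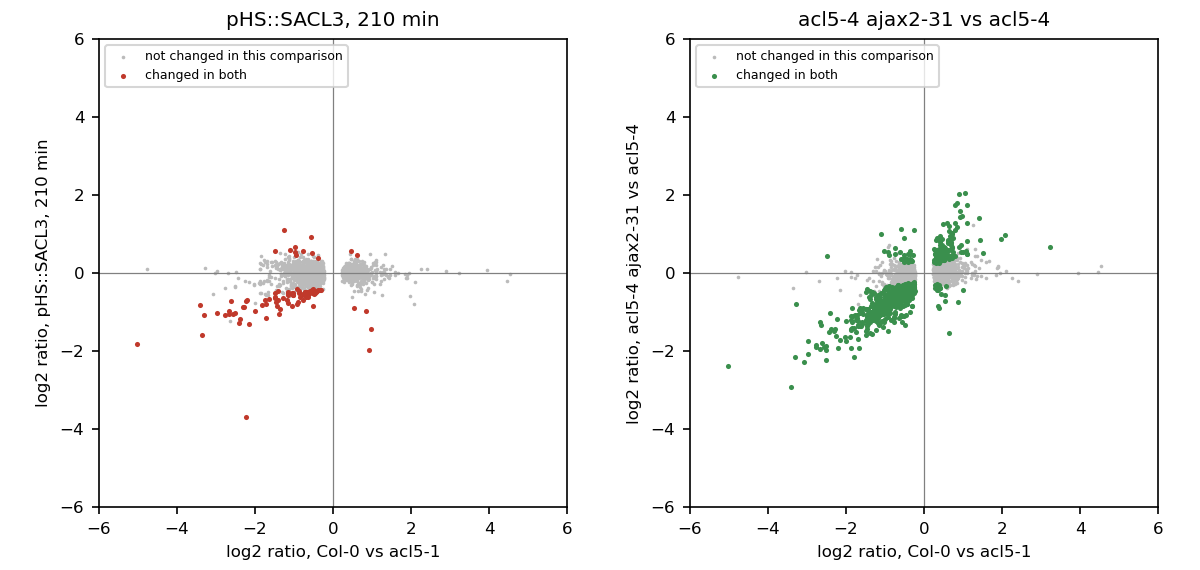
Log2 ratio of genes changed in Col-0 against acl5-1 (horizontal axis) against their log2 ratio at 210 min of pHS::SACL3 (left panel, vertical axis) and in acl5-4 ajax2-31 (right panel, vertical axis); coloured points changed in both comparisons and grey points in Col-0 alone. In the left panel 77 of the 93 coloured points are lower in both (7 genes without 210 min replicate 3), and in the right panel 599 of 794.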

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

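The tests of the difference between 30 min and 210 min of pHS::SACL3 were all chosen before their results were seen, and TBL38 was picked out without a test.

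These results stood out because the line behaved differently at the later time than at the earlier one. SACL3 fell by 6.77 on the log2 scale from 30 to 210 min (limma adjusted p = 5.36e-12), with 3 of 3 arrays high at 30 min. It carried its family list, whose mean difference was −2. The LHW-TMO5 module was lower at 210 min by a mean difference of −0.221, procambium and cambium by −0.151, auxin response by −0.106 and root genes by −0.0733. Xylem transcription factors (0.165), xylem secondary wall genes (0.153) and heat shock genes (0.222) were higher at 210 min. With an estimated correlation the SACL family (camera adjusted p = 0.00089) and the LHW-TMO5 module (0.0249) were called, and the other lists were not: adjusted p was 0.168 for procambium, 0.455 for xylem transcription factors and auxin response, and 0.542 for wall, heat shock and root genes. Fry did not call the LHW-TMO5 difference (fry adjusted p = 0.0821). The slides were not balanced between the times. Slide was fitted as a separate dye effect for each slide, which does not remove a shift of test over control by slide. The difference was then 0.0371 for xylem transcription factors (camera adjusted p = 0.263) and −0.0133 for wall genes (0.862), neither called. It was −0.291 for the LHW-TMO5 module, −0.138 for procambium, −0.179 for auxin response, 0.231 for heat shock and −0.141 for root genes, all called. Leaving out 1 array also ended the call of wall genes (0.115 without 30 min replicate 3 and 0.0728 without 210 min replicate 2) and of heat shock genes (0.0807 without 30 min replicate 3 and 0.101 without 210 min replicate 3), whose difference rose to 0.577 without 30 min replicate 1. Root genes lost theirs without replicate 1 or 3 of 30 min (−0.0564 and −0.0522) or replicate 1 or 2 of 210 min (−0.00361 and −0.0808), and stood at −0.189 without 210 min replicate 3. For heat shock genes the array medians at 30 min were 0.353, −0.545 and −0.595, and 0.211, −0.352 and −0.471 after removal of the fitted dye effect. The first of these arrays alone had the test genotype in Cy5 and lay on slide 3, so dye, slide and replicate are confounded. TBL38 had negative log2 ratios on all 3 arrays at 30 min and positive ones on all 3 at 210 min, a difference of 0.60; by that rule the difference was not tested, and in the test over all genes it did not pass (limma adjusted p = 0.256).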

How the results depend on the processing

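One alternative, leaving out genes within 5 Mb of ACL5, was chosen after seeing the data; with it 1963 genes changed in Col-0 and sign agreement was 52.8% at 30 min, 55.7% at 210 min and 76.5% in ajax2-31. Counts of genes shared between comparisons without 1 array were also added after seeing the data. Of 3352 tests of named genes under alternatives, 3066 kept direction and side of the threshold, 266 lost their call, 20 gained one and 0 reversed, where a value that passed no test counts as reversed only if called the other way. Of 612 tests of lists called in the 4 comparisons 557 stayed, 51 lost their call and 4 reversed; of 168 tests of lists called in the difference between times 144 stayed, 23 lost their call and 1 reversed, xylem secondary wall with slide fixed (−0.0133). Quantile scaling of brightness changed nothing, since it leaves ratios as they are. Where results moved, the cause was not tested, except that stricter thresholds lower counts by construction.

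Counts are given beside 2401 changed genes for Col-0, 13 at 30 min, 114 at 210 min, 1894 for ajax2-31 and 1 for the difference between times. Median centring gave 1422, 8, 48 and 12347 genes for the 4 comparisons. Before loess the median log2 Cy5 over Cy3 of the dimmest 1 in 5 and brightest 1 in 5 spots was 1.58 and −0.593 on ajax2-31 replicate 1, 1.48 and −0.572 on replicate 2, and −0.16 and 0.23 on replicate 3. Processed signals gave 3 genes at 30 min and 35 at 210 min, and the deposited log2 ratios of the series gave 3 and 36. Fits of single comparisons gave 1317 for Col-0, 63 at 210 min, 1026 for ajax2-31 and 5 for the difference. Array weights gave 35 at 30 min and 42 for the difference. Slide as a random block gave 181 at 210 min, 2941 for ajax2-31 and 35 for the difference; as a fixed block it gave 2849 for ajax2-31 and 36 for the difference. All 114 genes of 210 min and 1889 of the 1894 of ajax2-31 were called with the fixed block. Same-numbered replicates of different comparisons were not treated as paired in the main fit. Their deviations from the comparison means correlated from −0.634 to 0.348, and 4 of 18 pairs were above 0.1. Dye and slide are mixed into these values, so they cannot show whether equal numbers shared a batch. A replicate block with the dye term gave 6 genes at 30 min and 65 at 210 min, and in place of the dye term 6 for the difference. Without background correction or without the dye term the difference had 2 genes. With a 2-fold threshold counts were 307, 7, 19 and 199, and with treat at 1.5-fold 243, 2, 1 and 120.

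Leaving out 1 array gave 1411 to 1900 genes for Col-0, 2 to 11 at 30 min, 9 to 84 at 210 min, 891 to 1647 for ajax2-31 and 1 to 8 for the difference. Sign agreement then ran from 46.8% to 59% at 30 min, 46.9% to 65.5% at 210 min and 71.2% to 79.5% for ajax2-31. At 30 min it was 44.9% with array weights, 46.3% and 43.7% with slide as a random and a fixed block, and 70% of the 2-fold genes. For ajax2-31 it was 68.6% with median centring, 81.7% in single fits, 69.6% with array weights and 89.3% of the 2-fold genes. With an estimated correlation 13 list calls were left of 34. Reversed lists were xylem transcription factors at 30 min with slide fixed (mean 0.0101), heat shock genes at 30 min with array weights (−0.0261) and without replicate 3 (−0.0187; −0.489 to −0.0187 over the arrays left out), where camera's direction was up, and xylem secondary wall at 210 min without replicate 2 (−0.00722; up to 0.145 with others left out). Without 1 array, 7 to 11 of 52 named genes lost their call in Col-0, 4 to 8 of 10 at 30 min, 7 to 19 of 23 at 210 min and 5 to 12 of 54 in ajax2-31. SACL3 in Col-0 lost its call in 5 settings, at values from −0.43 to −0.30. Signal over background limits 4975 genes, which were too dim to test.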

Other observations

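The odds ratio around ACL5, the measures on each side of it, the time difference of MRD1 and the comparison of probe spread with the other comparisons were tests chosen after the results were seen; the remaining tests were chosen before.

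Changed genes of Col-0 against acl5-1 were crowded next to ACL5, with an odds ratio of 2.23 within 5 Mb either side; it was 4.96 above ACL5 and 1.14 below it. Inside, 65.3% of the 383 changed genes had the same sign in ajax2-31, against 76.1% of the 2018 outside (two-sided Fisher's exact test, p = 1.77e-05). This argues against a response to the loss of ACL5 that ajax2-31 reverses as often near ACL5 as elsewhere. A response that ajax2-31 does not reverse, or that differs in its Ler background, would also lower the share and stays open. On the side above, where the excess lay, the share was 60.1% of 243 (Fisher's exact test against outside, p = 2.29e-07). A candidate explanation is that acl5-1 carries a stretch of another accession next to ACL5, reaching mostly to one side, so that probes bind its transcripts unequally. Probes of a changed gene differed more inside (median SD 0.192 log2, 106 genes) than outside (0.0976, 579 genes; one-sided permutation p = 1e-05, the smallest that 100000 resamples can give), with 0.241 above ACL5 and 0.143 below. In other comparisons the same genes had SDs of 0.0547, 0.0623 and 0.067 inside and 0.053, 0.0521 and 0.0685 outside at 30 min, 210 min and in ajax2-31. This remains a hypothesis, since no sequence was examined and differences in expression level between accessions stay open beside probe binding.

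MRD1 was lower in the pHS::SACL3 line at both times (−2.99 and −3.70), and in Col-0 (−2.22) but not in ajax2-31 (−0.14). A lesion or insertion that takes in its neighbours stays open: of 42 tested genes within 100 kb, 1 changed, HEI10, at −0.21 (limma adjusted p = 1) at 30 min and −0.49 (adjusted p = 0.0092) at 210 min. HEI10 was also lower in Col-0 (−0.50, adjusted p = 0.000497) and not in ajax2-31 (−0.039, adjusted p = 0.834), as MRD1 was. A lesion in MRD1 alone would leave no trace among its neighbours. A response to induced SACL3 that builds up with time may apply too, but the difference between times was −0.71 (95% interval −1.45 to 0.0375), which includes 0. Neither a lesion in the pHS::SACL3 line nor induced SACL3 would account for the lower MRD1 and HEI10 in Col-0. Col-0 does not carry pHS::SACL3, and SACL3 was not higher there (−0.41). A difference between seed stocks of acl5-1 was not tested.

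Xylem secondary wall genes fell less on the reverse-labelled ajax2-31 array, with a median of −0.555 against −1.28 on the others. A dye effect of these genes shared by all slides is too small to be the main cause. Their median dye coefficient from the other comparisons was −0.0563 where −0.332 would be needed, or 17% of it. A dye effect particular to slide 3 stays open, because it held all ajax2-31 arrays and, of the other comparisons, only 30 min replicate 1. A difference between the plants of that replicate was not tested.

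Reversing the signs of single arrays gives too few patterns for a share under 0.05. For Col-0, 1 of 4 patterns gave as many genes as the real 2401, with 3 the highest of the others; for 30 min it was 1 of 4 (13, highest other 9), for 210 min 1 of 4 (114, highest other 0) and for ajax2-31 1 of 4 (1894, highest other 7). For the difference between times 3 of 10 splits of the 6 arrays gave as many as the real 1, the highest other being 1, which is also too few splits.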
